A study of Homo sapiens with 8 samples.

How the data were processed

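The intensity values were taken as deposited in the value table of the series. Per the labels, total RNA was turned into biotin-labelled cRNA and hybridised to Affymetrix human arrays. The software that made the deposited intensity per probe set was not stated. The deposited intensities were linear, and their mean without the highest and lowest 2% of values was 500.1 to 500.2 on each array, the scaling of Affymetrix signal software. Group, cell line, dose, time and replicate number came from the sample labels, and every one of the 8 arrays was used.

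Intensities were turned to log2 of the deposited value plus 50. The medians of the 8 arrays then ranged over 0.87 log2 units, more than the 0.5 allowed by a rule set before the data were examined, and quantile normalization was applied. Of 22277 probe sets, 62 controls were left out and 22215 were tested. The annotation gave 1 gene symbol for 19064 of them and several for 1043, and did not list 2108. Each of 11963 genes was represented by its probe set with the highest mean log2 value, with probe sets that may bind several transcripts taken only where a gene had no other (460 genes).

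Group means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3 on all 8 arrays, with 4 residual degrees of freedom, and the spread was moderated with an intensity trend (4.41 prior degrees of freedom). Contrasts were diclofenac minus DMSO in each line, their difference, and THP-1 minus HL-60 with DMSO. P-values were adjusted by Benjamini-Hochberg over the probe sets of a contrast, with 0.05 as the threshold, and errors are the moderated standard errors. The labels do not say whether replicate numbers pair arrays of the 2 treatments. Deviations of arrays with the same number correlated at -0.00 in HL-60 and -0.01 in THP-1, so no shared effect of the number was seen. The fit therefore had no replicate block.

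Lists were tested with camera of limma at a preset correlation of 0.01 and adjusted over 40 lists, of whose 826 genes 717 were measured, and again with a correlation estimated for each list. Members were also adjusted over the list alone, and a list's change is the median of its members. Relative changes are the list median minus the median of all genes under the same scaling. Centring subtracts 1 value per array, so the relative change is by construction the same on the deposited scale and under median centring. The tests, the lists, the threshold, the alternatives and the rule for named genes were fixed before the data were examined. That rule took up to 10 genes per direction in each line and 5 in the other contrasts, up to 4 members per list, the AP-1 family, 9 single genes and up to 5 genes per direction changed in both lines. The background measure, the fit without both THP-1 DMSO arrays, the overlap at an unadjusted p and the count of list members that differed between the untreated lines were chosen after. Background was the 95th percentile of 27 bacterial control probe sets with no target in the samples, per array. Where a gene was above it on no array of 1 group the change is given as a lower bound of the fold, and where it was above it in neither group no fold is given.

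Alternatives were the deposited values without quantile normalization, median centring, an offset of 16 or none, the dimmest 40% of probe sets left out, no intensity trend, a replicate block, each line fitted alone, a minimum log2 change of 1, the mean of a gene's probe sets and each array left out in turn. The method was tested on simulated data with 200 changed probe sets per comparison and 20 runs, with the excess scatter of THP-1 DMSO placed on replicate 2 or on both arrays. A list of 29 genes shifted by 0.4 log2 units was called in 20 of 20 runs in both lines, and 0 of 800 unshifted lists were called. The simulated probe sets varied independently of each other. These runs therefore cannot show how often lists of correlated genes are falsely called at the preset correlation. Random lists matched on mean log2 value were drawn 10000 times. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.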

Results

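Gene expression was measured with 8 single-colour Affymetrix human arrays in HL-60 and THP-1 cells. Cells received 100 µM diclofenac, an anti-inflammatory drug that inhibits the cyclooxygenases, or its solvent DMSO for 48 h, with 2 arrays per group titled as biological replicates. The lines are named here as the labels give them, and the marker genes given with the untreated lines below did not settle that the cells were of the type each label names. The deposited value table held 1 intensity for each of 22277 probe sets per array, from 0.1 to 39370.8, and the number of arrays limits the precision. The median intensity of the HL-60 DMSO arrays was 150.2 and 117, that of the HL-60 diclofenac arrays 115.4 and 111.6, and that of the THP-1 diclofenac arrays 123.3 and 114.2. THP-1 DMSO replicate 1 had a median of 109.6 and replicate 2 of 241.2. The values were linear and each array had been scaled to 1 mean, and no centring across arrays was present. The software behind this scale stayed unknown, and a direction was not in question because each column holds 1 sample.

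THP-1 DMSO replicate 2 stood apart from the other 7 arrays. Bacterial control probe sets with no target in the samples had a median of 78 on it and of 5.6 to 24.6 on the others. It had 50.32% of probe sets above the background of its own array, against 66.36% to 72.14% elsewhere. Its correlation across probe sets with replicate 1 was 0.898, whereas the other 3 pairs of replicates had 0.977 to 0.984. The median absolute difference between replicates was 0.451 log2 units in THP-1 DMSO and 0.156 to 0.203 in the other groups. Every THP-1 comparison below sets the diclofenac arrays against this pair, so values without replicate 2 stand beside the results that it changes. After quantile normalization the median change of all genes was within 0.01 log2 units of 0 in each line. It was -0.06 in HL-60 and -0.16 in THP-1 on the deposited scale, and 0.11 and 0.20 with each array centred on its median. Among bright genes alone it was -0.01 and -0.03 on the deposited scale, and 0.15 and 0.33 with centring. Gene list changes under these scalings are given relative to the shift of all genes, so the 2 scalings give the same value. A list of bright genes can lie above all genes and still below bright genes.

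**Figure D1:**
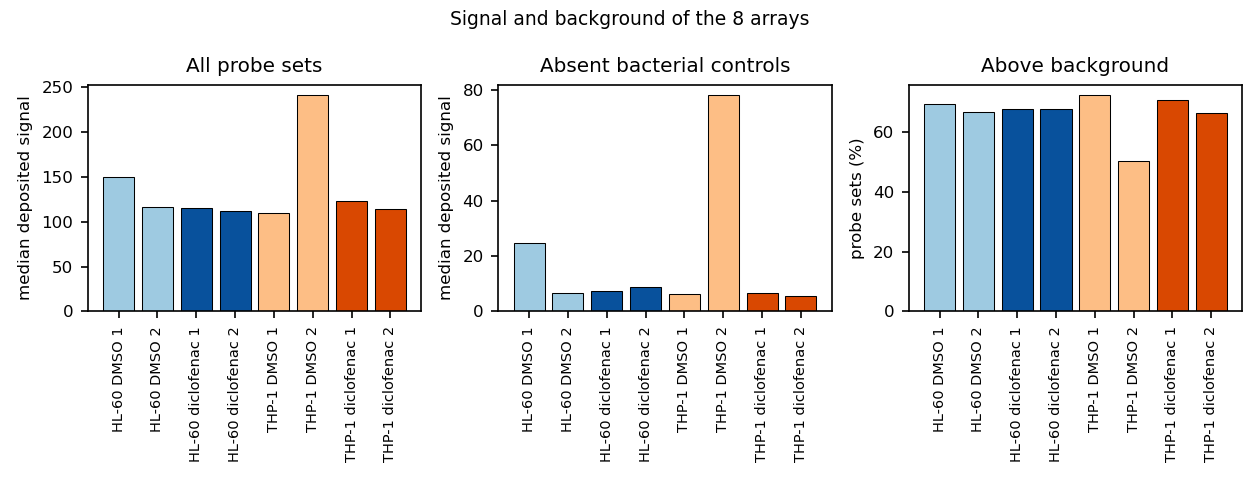
Bars show, for each of the 8 arrays, the median deposited signal of all probe sets, the median deposited signal of bacterial controls absent from the samples, and the percentage of probe sets above the array's own background. THP-1 DMSO replicate 2 had a control median of 78, against 5.6 to 24.6 on the other arrays.

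The HL-60 comparison asked which transcripts differed after diclofenac on the arrays labelled HL-60. PLIN2, the coat protein of lipid droplets, rose 2.58-fold in HL-60 (log2 fold change 1.37 ± 0.08, SE, n = 2 arrays per group, limma adjusted p = 0.0028). Its signal was 2645 and 2584.4 with DMSO and 7040.7 and 7634.8 with diclofenac, whereas a second, dimmer probe set of PLIN2 had a log2 change of -0.26. The amino acid response genes controlled by the transcription factor ATF4 rose together, with a median log2 change of 0.39 and 25 of 29 members above 0. The myeloid surface peptidase ANPEP, named after its values were seen, had a log2 change of 1.81 ± 0.19 at an adjusted p of 0.055.

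With limma and Benjamini-Hochberg adjustment over 22215 probe sets, 1 rose and 0 fell in HL-60, while 528 were higher and 472 lower at an unadjusted p under 0.05, where chance gives 1111 in all. The count was 0 under median centring and without the intensity trend. Leaving out any of the 4 HL-60 arrays left no call, and the adjusted p of PLIN2 was then 0.059 to 0.11. Without THP-1 DMSO replicate 2, which enters the shared estimate of the spread, 5 probe sets rose and 1 fell, and without THP-1 DMSO replicate 1 the numbers were 10 and 1. The genes without replicate 2 were ANPEP (1.86), ASNS (1.65), PLIN2 (1.38), HMOX1 (1.08) and CSTA (0.77), which rose, and 1 probe set of MTDH (-0.96), which fell. On simulated arrays with this spread, 36.3% of changes of 1.5 log2 units and 60.6% of changes of 2 log2 units in HL-60 were called.

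In HL-60, 7 of the 40 gene lists passed limma's camera test at a preset correlation, 6 upward and 1 downward. The list of ATF4 and amino acid response genes had a camera adjusted p of 6.3e-19, and of 0.018 with an estimated correlation. None of its 29 members passed over all probe sets, and 13 rose when adjusted over the list alone. ASNS, the asparagine synthetase, had a log2 change of 1.58 ± 0.35 (adjusted p = 0.62 over all probe sets), and PHGDH, which opens serine synthesis, one of 0.76 ± 0.11 (0.14). The cystine transporter gene SLC7A11 (0.64), the neutral amino acid transporter gene SLC7A5 (0.70), the pseudokinase gene TRIB3 (0.71) and ATF4 itself (0.71) were also among the 13. These 4, like the other members named below for passing over a list alone, were chosen after their values were seen.

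The other HL-60 list calls were smaller and were lost with an estimated correlation. Ribosomal protein genes had a median of 0.09 with 21 of 25 members above 0 (adjusted p = 1.5e-05, and 0.14 with an estimated correlation), and 0 members passed alone. Heme and iron genes had a median of 0.14 (0.0048, and 0.21 with an estimated correlation) and 0 members past the test alone, and this call was lost without HL-60 diclofenac replicate 2 (0.061). Cholesterol synthesis genes had a median of 0.11 (0.02, and 0.26 with an estimated correlation), and MSMO1 (0.80) and HMGCS1 (0.64) rose when adjusted over the list alone. PPAR targets and fatty acid oxidation genes had a median of 0.15 (0.02, and 0.78 with an estimated correlation). In that list PLIN2 passed over all probe sets, and PLIN2 and FABP4 (1.88 ± 0.34), 2 lipid-binding proteins, rose when adjusted over the list alone. Metallothionein genes had a median of 0.17 (0.021, and 0.78 with an estimated correlation), with the zinc exporter SLC30A1 (0.60) past the test alone. The cholesterol, PPAR and metallothionein calls were lost without HL-60 DMSO replicate 2 (0.22, 0.079 and 0.32) and without HL-60 diclofenac replicate 1 (0.094, 0.29 and 0.13).

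Primary granule and promyelocyte genes fell in HL-60 by a median of 0.15 (adjusted p = 0.0022, and 0.21 with an estimated correlation). Relative to all genes the median was -0.04 without quantile normalization. The list median itself was -0.10 on the deposited scale, where bright genes had -0.01 and the call was lost (camera adjusted p = 0.81). Under centring, which moved all genes by 0.11 and bright genes by 0.15, the list median was 0.06. Of 14 members, 6 fell and 1 rose when adjusted over the list alone. MS4A3 (-0.66), the granule proteins AZU1 (-0.37), CTSG (-0.33) and PRTN3 (-0.21), the transcription factor MYB (-0.26) and the proteoglycan SRGN (-0.21) fell, and the complement protease CFD (0.74) rose. Under median centring only ATF4 targets (7.6e-09) and heme and iron genes (0.029) were called in HL-60.

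The THP-1 comparison asked the same of the arrays labelled THP-1. IFI6, an interferon-stimulated gene, rose 5.99-fold in THP-1 (2.58 ± 0.34 log2 units, SE, n = 2 arrays per group, limma adjusted p = 0.042), and DENND4B rose 5.41-fold (2.44 ± 0.27, 0.022). PLIN2 rose 2.91-fold (1.54 ± 0.08, 0.001) by its representative, whereas its dimmer probe set had -1.18 (-0.65 without THP-1 DMSO replicate 2) and was not called. ANXA1, a phospholipid-binding protein of myeloid cells, rose 2.8-fold (1.49 ± 0.10, 0.0027), and CEBPB, a transcription factor of monocyte differentiation, 2.25-fold (1.17 ± 0.11, 0.012). Inflammatory, immediate early, interferon, monocyte and lysosome lists rose together, with list medians of 0.28 to 0.55, and each of these 5 calls was lost with an estimated correlation (0.062 to 0.099). CTSG, a granule protease, was the 1 gene that fell (-0.53 ± 0.07, 0.035), and no probe set was called downward on the deposited scale or with a replicate block.

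In all, 29 probe sets rose and 1 fell in THP-1 at an adjusted p of 0.05, which gave 19 genes up and 1 down among 11963 representatives, and 2359 probe sets had an unadjusted p under 0.05. No probe set was called in THP-1 under median centring, without the intensity trend or with the line fitted alone. TNFRSF21, a death receptor, was not above background on the DMSO arrays and rose at least 2.64-fold. KLF10 (1.65 ± 0.23), an early transcription factor, NDUFB7 (1.70 ± 0.23) of respiratory complex I, the glycoprotein gene GPNMB (1.18 ± 0.11) and ACSL1 (1.12 ± 0.11), which activates long-chain fatty acids, also rose. A dimmer probe set of NDUFB7 had -1.13 (-0.71 without THP-1 DMSO replicate 2) and was not called. The survival gene BCL2A1 (1.09), the leukotriene synthesis gene ALOX5AP (1.04), the lysosomal gene PSAP (0.92) and the MAPK phosphatase gene DUSP6 (0.89) were further members of fixed lists that rose. LAP3, S100A11, RAB13, NPTN and the ferritin pseudogene FTH1P5 complete the 19, with 0.55 to 0.97, and are named after their values were seen. Further probe sets of SAT1, CD36, HMGN4, MCL1, MTDH and RIOK3, named likewise, passed while the representative did not. For MCL1, MTDH and RIOK3 the representative had a log2 change of 0.07 (0.32 without THP-1 DMSO replicate 2), -0.03 and 0.21.

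Without THP-1 DMSO replicate 2, 57 probe sets rose and 3 fell, and 28 of the 30 were called again in the same direction. IFI6 then had a log2 change of 2.05, DENND4B of 3.05, CEBPB of 1.07 and CTSG of -0.59. The count was 6892 without THP-1 DMSO replicate 1, when replicate 2 stands alone for its group. It was 2 without either HL-60 DMSO array, 3 without either HL-60 diclofenac array, 1 without THP-1 diclofenac replicate 1 and 0 without replicate 2. On simulated arrays 1.2% of THP-1 calls were false when the excess scatter lay on THP-1 DMSO replicate 2, and 30.5% when it lay on both arrays of that group. Pairs of arrays of the same line without replicate 2 correlated at 0.972 to 0.984, and replicate 2 with the other THP-1 arrays at 0.894 to 0.898, which places the excess on replicate 2.

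**Figure D2:**
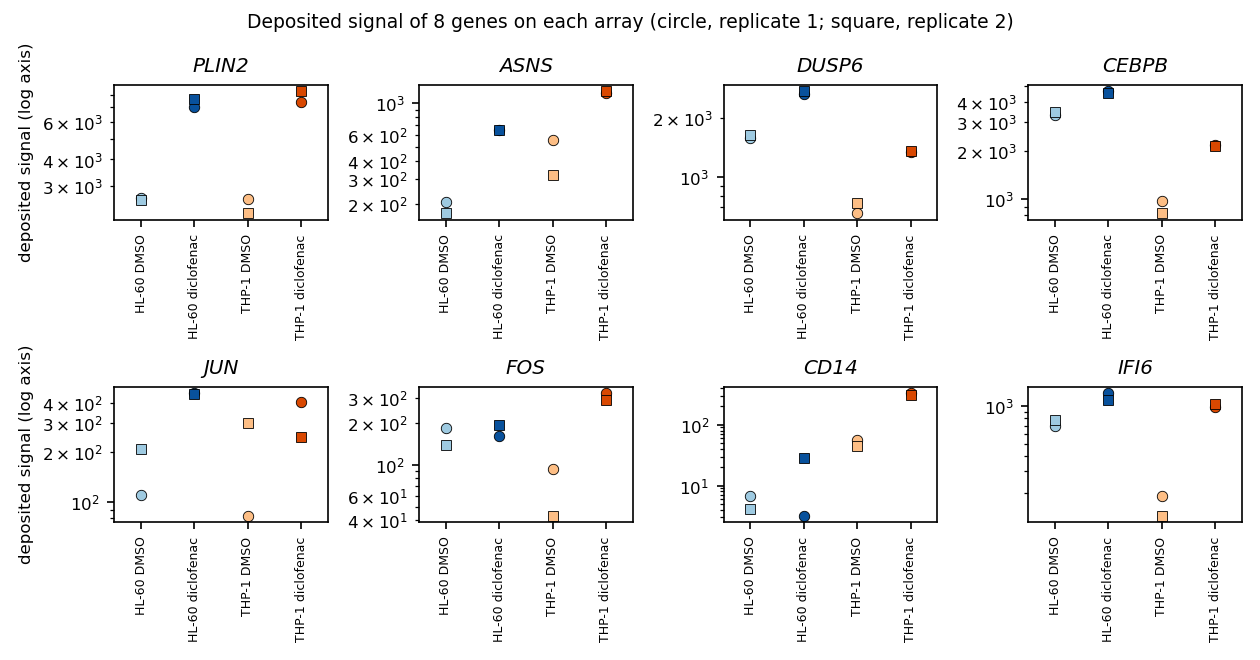
Points show the deposited signal on a log axis of 8 genes on each array, with circles for replicate 1 and squares for replicate 2 of the 4 groups. The signal of PLIN2 was 2246.3 to 2645 on the 4 DMSO arrays and 7040.7 to 8348.2 on the 4 diclofenac arrays.

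In THP-1, 14 of the 40 lists passed camera, 12 upward and 2 downward, and none did with an estimated correlation. THP-1 DMSO replicate 2 lay on the control side of every one of these values, and 10 of the 14 were called again without it. NF-kB and inflammatory cytokine genes had a median of 0.55, and of 0.34 without THP-1 DMSO replicate 2, with 24 of 27 members above 0 (camera adjusted p = 1.9e-07, and 0.062 with an estimated correlation). None of them passed over all probe sets, and 7 rose when adjusted over the list alone, among them IL1B (1.42 ± 0.29) and the NF-kB inhibitors TNFAIP3 (0.84) and NFKBIA (0.79). The chemokine CCL2 rose at least 1.28-fold on the same test. CXCL8 rose at least 2.4-fold by its representative, whereas its other, brighter probe set had -0.10 (-0.22 without THP-1 DMSO replicate 2). Immediate early and MAPK feedback genes had a median of 0.47 with 23 of 25 above 0 (1.9e-07, and 0.062 with an estimated correlation). KLF10 and DUSP6 passed over all probe sets and 8 rose when adjusted over the list alone, including EGR1 (1.01 ± 0.21), KLF4 (1.29 ± 0.29), PLAUR (0.79) and SGK1 (1.76 ± 0.45). KLF4 had 0.84 and SGK1 1.05 without THP-1 DMSO replicate 2.

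Interferon response genes had a median of 0.52 with 21 of 30 above 0 in THP-1 (adjusted p = 0.00019, and 0.071 with an estimated correlation). IFI6 passed over all probe sets, and 6 rose when adjusted over the list alone, with ISG15 at 0.85, IFITM3 at 1.53 (0.85 without THP-1 DMSO replicate 2) and IFIT1 at least 1.84-fold higher. Monocyte and macrophage markers had a median of 0.40, and of 0.27 without THP-1 DMSO replicate 2, with 22 of 32 above 0 (0.00033, and 0.099 with an estimated correlation). None of the 32 passed over all probe sets. Adjusted over the list alone 9 rose, among them CD14, a receptor for lipopolysaccharide (2.18 ± 0.40, and 1.76 without THP-1 DMSO replicate 2), CD36 (1.12 ± 0.16) and MMP9 (0.95 ± 0.20), and the transcription factor IRF8 fell (-0.35). The CD14 signal was 55.6 and 45.2 with DMSO, above background on replicate 1 alone, and 332.9 and 310.5 with diclofenac. Lysosome and autophagy genes had a median of 0.28 with 25 of 29 above 0 (1.1e-07, and 0.065 with an estimated correlation). PSAP passed over all probe sets, and 9 rose when adjusted over the list alone, including the cathepsin genes CTSB (0.87) and CTSD (0.85, and 0.47 without THP-1 DMSO replicate 2), the sialidase gene NEU1 (0.99) and the autophagy receptor gene SQSTM1 (0.57). The interferon call was lost without THP-1 DMSO replicate 1 (0.058).

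The ATF4 and amino acid response list rose in THP-1 as well, with a median of 0.28 and 25 of 29 members above 0 (adjusted p = 4.3e-06, and 0.062 with an estimated correlation). CEBPB passed over all probe sets. Adjusted over the list alone 9 rose and 1 fell, with ASNS at 1.61 ± 0.35 (1.00 without THP-1 DMSO replicate 2), SLC7A11 at 0.98 ± 0.17 and the serine synthesis gene PSPH at -0.53, though 0.32 by its other probe set (0.20 without THP-1 DMSO replicate 2). Relative to all genes, the list median was 0.46 in HL-60 and 0.45 in THP-1 without quantile normalization. NRF2 targets and oxidative stress genes had a median of 0.17 with 18 of 24 above 0 in THP-1 (0.0016, and 0.099 with an estimated correlation). Of them 4 rose when adjusted over the list alone, HMOX1 (1.41 ± 0.29), GCLC (0.81), SLC7A11 and PGD (0.53). A second probe set of GCLC had -0.20 (0.17 without THP-1 DMSO replicate 2). HMOX1 had 0.93 and the GCLC representative 0.46 without that array, and the list's call was lost without THP-1 DMSO replicate 1 (0.16).

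The AP-1 family, the JUN, FOS and related transcription factors fixed before the data were examined, had a median of 0.54 in THP-1 with 10 of 12 members above 0 (adjusted p = 0.0014, and 0.17 with an estimated correlation). The median was 0.31 without THP-1 DMSO replicate 2, with the list still called (0.005). FOS had a log2 change of 1.92 ± 0.47 (adjusted p = 0.25 over all probe sets, and past the test when adjusted over the list alone), which was 1.26 without THP-1 DMSO replicate 2. JUN had 1.03 ± 0.39 (0.43) in THP-1 and 1.37 ± 0.39 (0.76) in HL-60, with both diclofenac arrays of HL-60 above both of its DMSO arrays. Other JUN probe sets had 1.35, 0.41 and 0.35 in HL-60, the last being the brightest. In THP-1 the same probe sets had 1.64, 0.71 and 1.42 (1.49, 0.56 and 0.71 without THP-1 DMSO replicate 2). The THP-1 values of the other members were 0.50 for JUNB, 0.28 for JUND, 0.59 for FOSL1, 0.42 for FOSL2, 0.69 for ATF3, 0.68 for BATF, 1.04 for MAFF, -0.05 for ATF2 and -0.10 for MAFG. The values of FOSL1 (-0.09), BATF (-0.27) and MAFG (0.09) changed sign without THP-1 DMSO replicate 2, when JUNB had 0.28, ATF3 1.06, MAFF 0.50 and JUN 1.41. The other MAFF probe set had 2.08 in THP-1 (1.62 without THP-1 DMSO replicate 2). FOSB was above background on 1 of the 8 arrays. In HL-60 the list median was 0.06 (0.33), and no member passed the test alone. The HL-60 values were 0.22 for FOS, 0.07 for JUNB, 0.31 for JUND, -0.02 for FOSL1, -0.12 for FOSL2, 0.17 for ATF3, -0.25 for BATF, -0.33 for MAFF (0.40 by its other probe set), 0.22 for ATF2 and 0.04 for MAFG.

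Other upward lists in THP-1 rested more on single arrays. PPAR targets and fatty acid oxidation genes had a median of 0.24 (adjusted p = 0.0012, and 0.36 with an estimated correlation), and PLIN2, CD36 and the nuclear receptor PPARG (1.14 ± 0.22) rose when adjusted over the list alone. Metallothioneins had 0.29 (0.011, and 0.53 with an estimated correlation), with MT1H (0.53) past the test alone. Pro-apoptotic genes had 0.19 (0.042, and 0.53 with an estimated correlation), with 0 members past the test alone. Without THP-1 DMSO replicate 2 these 3 calls were lost, at 0.12, 0.36 and 0.87, with medians of 0.15, 0.06 and -0.01. The metallothionein call was also lost without THP-1 diclofenac replicate 2 (0.088), and the pro-apoptotic call without either HL-60 DMSO array (0.062 and 0.06) or THP-1 diclofenac replicate 2 (0.11). Under median centring the metallothionein (0.13) and pro-apoptotic (0.098) calls were lost and the PPAR call was kept (0.0015), and all 3 were kept on the deposited scale. Prostaglandin and leukotriene genes had 0.13 (0.038, and 0.2 with an estimated correlation) but -0.09 on the deposited scale, which is 0.06 relative to all genes. ALOX5AP passed over all probe sets, and ALOX5AP and the prostaglandin receptor gene PTGER4 (0.59) rose when adjusted over the list alone. This call was lost on the deposited scale (0.18), under median centring (0.23), without THP-1 DMSO replicate 1 (0.33) and without THP-1 diclofenac replicate 2 (0.11). Among the drug's targets, PTGS1 had a log2 change of 0.01 ± 0.34 in HL-60 and -0.25 ± 0.34 in THP-1 (0.33 without THP-1 DMSO replicate 2). PTGS2 had -0.02 ± 0.32 in HL-60 and was not above background with DMSO in THP-1.

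DNA replication and S phase genes fell in THP-1 by a median of 0.23 with 26 of 31 members below 0 (adjusted p = 9.2e-06, and 0.099 with an estimated correlation). Their median relative to all genes was 0.07 without quantile normalization. The list median itself was -0.09 on the deposited scale, where bright genes had -0.03, and 0.27 under centring, where bright genes had 0.33. CCNE1 (-0.83 ± 0.19), the G1 cyclin, GINS1 (-0.64) and RRM2 (-0.48), a ribonucleotide reductase subunit, fell when adjusted over the list alone. Oxidative phosphorylation genes fell by a median of 0.11 (0.0062, and 0.24 with an estimated correlation), but their median relative to all genes was 0.22 without quantile normalization. The list median itself was 0.06 on the deposited scale, and 0 of 37 members passed alone. The downward calls of replication and oxidative phosphorylation genes were lost on the deposited scale (camera adjusted p = 0.25 and 0.056). They were also lost under median centring (0.68 and 0.15). The replication call was lost without THP-1 DMSO replicate 1 (0.077), and the oxidative phosphorylation call without either THP-1 DMSO array (0.077 and 0.069). Mitosis genes (-0.12, adjusted p = 0.07) and MYC and ribosome biogenesis genes (0.01, 0.48) were called downward in THP-1 when THP-1 DMSO replicate 2 was left out (-0.15, 0.00048 and -0.13, 0.017). The mitosis list was also called without the dimmest probe sets (0.025), but had a median of 0.07 relative to all genes without quantile normalization. Its median itself was -0.08 on the deposited scale, where bright genes had -0.03. A 28S ribosomal RNA control was higher in THP-1 with diclofenac, at 11803.7 and 10775.7 against 3106.7 and 1875.7, a log2 difference of 2.22. The difference was 1.86 against THP-1 DMSO replicate 1 alone, and 0.30 in HL-60. Another 28S control differed less in THP-1, at 3677.5 and 2572 against 1300.3 and 990. An 18S control had 5657.7 and 4535.5 against 4414.1 and 2791.7.

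**Figure D3:**
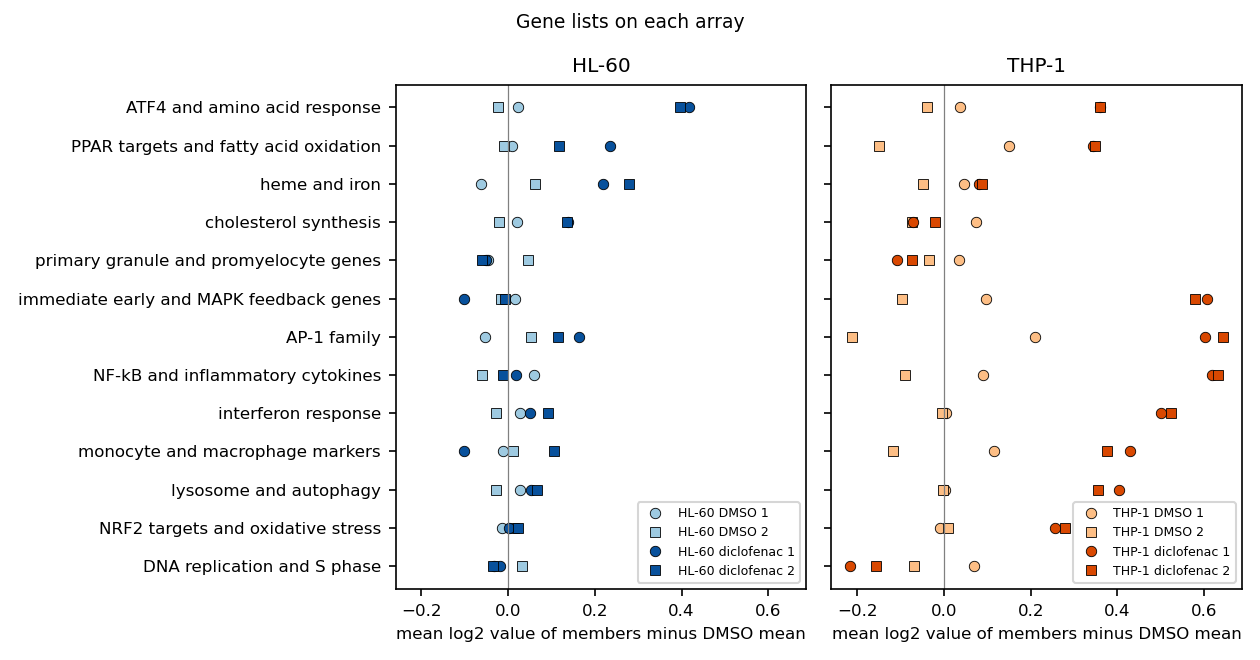
Points show, for 13 gene lists in each line, the mean log2 value of the members on each array minus the mean of the 2 DMSO arrays of that line, with circles for replicate 1 and squares for replicate 2. The DNA replication list lay below 0 on both THP-1 diclofenac arrays after quantile normalization. Without that normalization its median was 0.07 relative to all genes, and its downward call was lost. The median itself was -0.09 on the deposited scale, where bright genes had -0.03.

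The lists called in 1 line had these values in the other. In THP-1, ribosomal protein genes had a median of -0.05 (adjusted p = 0.25), cholesterol synthesis genes -0.06 (0.48, and -0.21 without THP-1 DMSO replicate 2), heme and iron genes 0.02 (0.92, with HMOX1 past the test alone) and primary granule genes -0.00 (0.18, and -0.04 without that array). In the granule list CTSG fell over all probe sets, and CTSG, MS4A3 (-0.49) and ELANE (-0.20) fell when adjusted over the list alone. In HL-60, the medians were -0.06 for immediate early genes (0.95, with DUSP6 at 0.71 past the test alone), -0.02 for NF-kB genes (0.95), 0.11 for interferon genes (0.87), 0.05 for monocyte markers (0.96) and 0.01 for lysosome genes (0.5). They were -0.01 for NRF2 targets (0.95), where HMOX1 (1.07) and SLC7A11 rose and PRDX1 (-0.36) fell when adjusted over the list alone. Pro-apoptotic genes had -0.04 (0.95, with TXNIP at 0.82 past the test alone), prostaglandin genes -0.04 (0.95), DNA replication genes -0.06 (0.44) and oxidative phosphorylation genes 0.05 (0.11).

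No other list was called in either line. ER chaperone genes had a median of -0.12 in HL-60 (adjusted p = 0.054) and 0.08 in THP-1 (0.16), and were called downward in HL-60 without THP-1 DMSO replicate 2 (0.04), without THP-1 DMSO replicate 1 (0.042) and without HL-60 diclofenac replicate 2 (0.019). Under the deposited scale and median centring their medians relative to all genes were -0.02 in HL-60 (0.64 and 0.96) and 0.36 in THP-1. In THP-1 the list was then called upward (0.0022 and 0.013). The THP-1 list medians themselves were 0.20 and 0.56, where bright genes had -0.03 and 0.33. The p53 targets had -0.01 and 0.28 (0.95 and 0.071, and a THP-1 median of -0.06 without THP-1 DMSO replicate 2), anti-apoptotic genes 0.11 and -0.20 (0.68 and 0.91), neutrophil maturation genes -0.00 and 0.02 (0.96 and 0.1), and hypoxia genes -0.08 and 0.22 (0.34 and 0.092). Mitosis genes had -0.05 (0.34) and MYC and ribosome biogenesis genes 0.03 (0.57) in HL-60. Fatty acid synthesis genes had 0.10 and -0.02 (0.44 and 0.83), LXR targets 0.11 and 0.23 (0.34 and 0.16), glycolysis genes 0.01 and -0.04 (0.88 and 0.48) and heat shock genes 0.02 and -0.10 (0.98 and 0.25). LXR targets were called in HL-60 without HL-60 DMSO replicate 2 (0.032). MHC class II genes had -0.05 and 0.17 (0.51 and 0.56), histone genes 0.05 and -0.10 (0.95 and 0.56), the HOXA and MEIS1 program 0.01 and -0.09 (0.95 and 0.48) and xenobiotic metabolism genes -0.00 and -0.09 (0.95 and 0.74). Markers of other cell types had, in HL-60 and THP-1, -0.08 and -0.13 for eosinophils and basophils (0.87 and 0.51), 0.12 and -0.07 for erythroid cells (0.75 and 0.92), and -0.07 and -0.12 for megakaryocytes (0.69 and 0.66). T cell markers had 0.12 and -0.22 (0.22 and 0.56), B cell markers -0.18 and 0.05 (0.69 and 0.83), epithelial markers 0.01 and 0.08 (0.68 and 0.91) and fibroblast genes -0.06 and -0.03 (0.87 and 0.66). The THP-1 median without THP-1 DMSO replicate 2 was 0.32 for T cell markers, with 11 of 13 members above 0, -0.00 for LXR targets, -0.28 for the HOXA and MEIS1 program, 0.05 for xenobiotic and for erythroid genes, 0.12 for fibroblast genes and -0.02 for eosinophil markers. It was 0.13 for hypoxia genes, -0.18 for histones, -0.07 for fatty acid synthesis, -0.03 for heat shock genes, -0.02 for megakaryocyte and 0.01 for B cell markers. The deposited scale added upward calls for oxidative phosphorylation (6.8e-05) and lysosome genes (0.017) in HL-60, and for hypoxia (0.028) and ribosomal protein genes (0.028) in THP-1. Without the dimmest probe sets, ER chaperones in HL-60 (0.043, downward) and neutrophil (0.042), hypoxia (0.021) and histone genes (0.04, downward) in THP-1 were called. THP-1 then had 16 called lists, 12 upward and 4 downward, and 2 upward calls of the main fit were lost. The median, mean and test direction differed in sign for 12 lists in HL-60, 7 in THP-1 and 6 in the difference between lines, of which 0 were called.

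In these uncalled lists, BCL2A1 and ACSL1 rose in THP-1 over all probe sets, as given above, and no other member did. Adjusted over the list alone, APOE (2.05 ± 0.60, and 1.14 without THP-1 DMSO replicate 2) and APOC1 (1.04) of the LXR list rose in THP-1. Other probe sets of APOE had 1.12 and 0.33 (0.79 and 0.46 without that array). FN1 (2.13 ± 0.46) and SPARC (0.88) of the fibroblast and matrix list, ABCC1 (0.75) of the xenobiotic list and MXI1 (0.49) of the hypoxia list rose too. A second SPARC probe set had 0.06 (-0.12 without THP-1 DMSO replicate 2). Other FN1 probe sets had 0.17 to 2.24 (-0.18 to 1.25 without that array). LOX of the hypoxia list fell by at least 1.48-fold (0.50 and 0.01 by its other 2 probe sets, and 0.20 and 0.15 without THP-1 DMSO replicate 2), H2AC17 (1.35) rose and H2BC12 (-0.63) fell among histone genes, and NIP7 (0.84, and 0.54 without THP-1 DMSO replicate 2) rose while FBL (-0.52) and WDR12 (-0.32) fell among MYC and ribosome biogenesis genes. Of the single genes fixed before the data were examined, CD14 was not above background in HL-60, and MYC had -0.03 ± 0.10 in HL-60 and -0.25 ± 0.10 in THP-1. ITGAM had 0.18 and 0.39, ITGAX 0.18 and 0.18 (-0.52 without THP-1 DMSO replicate 2), CSF1R 0.37 and -0.23 (-0.13 without it), CEBPB 0.39 and 1.17, and GADD45A 0.33 and 0.03 (0.71 without THP-1 DMSO replicate 2), in HL-60 and THP-1.

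The interaction test asked whether the lines responded differently. Immediate early genes (median difference 0.63, THP-1 change minus HL-60 change), NF-kB and inflammatory genes (0.54), interferon genes (0.46), monocyte markers (0.36) and lysosome genes (0.34) changed more in THP-1. Their camera adjusted p values were 1.1e-05, 1.3e-05, 0.0029, 0.0022 and 1.3e-05, and were 0.13, 0.13, 0.13, 0.16 and 0.13 with an estimated correlation. Adjusted over the list alone, 5, 1, 0, 3 and 3 members passed, among them EGR1 (1.44 ± 0.30), KLF4 (1.40 ± 0.42), MMP9 (1.27 ± 0.29) and LIPA (0.65 ± 0.15). All 5 were called again without THP-1 DMSO replicate 2, with medians of 0.60, 0.47, 0.36, 0.31 and 0.36, and the interferon call was lost without THP-1 DMSO replicate 1 (0.09). Among single probe sets 1 of MTDH passed (1.79 ± 0.15, limma adjusted p = 0.039, named after its values were seen), while its other 2 probe sets had -0.22 and 0.06. No gene passed by its representative, and 1542 probe sets had an unadjusted p under 0.05. The MTDH call was lost without any 1 of the 4 HL-60 and 2 THP-1 diclofenac arrays, under median centring, without the intensity trend and with a replicate block. Of the other fits, 4042 probe sets passed without THP-1 DMSO replicate 1, and 4 did without replicate 2, of DENND4B (2.93), MTDH (1.87), ANXA1 (1.40) and S100P (1.25).

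A further 7 of the 12 lists called in the interaction had smaller differences. NRF2 targets (0.30, adjusted p = 0.0049, and 0.14 with an estimated correlation), ER chaperones (0.20, 0.013, and 0.17) and hypoxia genes (0.26, 0.034, and 0.19) were higher in THP-1. Under median centring the hypoxia call was lost (0.18), and the NRF2 and ER chaperone calls were kept (0.033 each). Ribosomal protein genes (-0.10, 0.00061, and 0.13 with an estimated correlation), oxidative phosphorylation genes (-0.13, 0.0011, and 0.17), DNA replication genes (-0.14, 0.0056, and 0.2) and cholesterol synthesis genes (-0.24, 0.04, and 0.19) were lower in THP-1, but relative to all genes under the other scalings their medians were -0.04, 0.03, 0.02 and -0.05. On the deposited scale the list medians themselves were -0.14, -0.07, -0.08 and -0.14, and bright genes had -0.03. None of these 4 lists was called under either scaling. Over the list alone, 0 members of the NRF2, ER chaperone, hypoxia and oxidative phosphorylation lists passed, RPL35 (-0.40) and RPS9 (-0.36) were lower, and MSMO1 (-1.07 ± 0.19) was lower. Of the replication genes PCNA (0.81) was higher and 5 were lower, among them CCNE1 (-0.99) and RRM2 (-0.59). Each of these 7 calls was lost without THP-1 DMSO replicate 1, at 0.11, 0.09, 0.11, 0.14, 0.056, 0.31 and 0.46. The ER chaperone call was also lost without HL-60 diclofenac replicate 1 (0.078), and the hypoxia call without HL-60 DMSO replicate 1 (0.066), HL-60 diclofenac replicate 2 (0.068) or THP-1 diclofenac replicate 1 (0.069). The cholesterol call was lost without HL-60 DMSO replicate 2 (0.09), HL-60 diclofenac replicate 1 (0.065) or THP-1 diclofenac replicate 1 (0.077).

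Of the remaining 28 lists, the AP-1 family had a median difference of 0.50 (adjusted p = 0.13, and 0.034 under median centring), which was 0.13 without THP-1 DMSO replicate 2, the amino acid response list -0.07 (0.31) and prostaglandin genes 0.44 (0.087). Pro-apoptotic genes had 0.31 (0.17, but 0.029 without THP-1 DMSO replicate 1), neutrophil genes 0.26 (0.17, but 0.043 without HL-60 diclofenac replicate 2), p53 targets 0.20 (0.13) and PPAR targets 0.13 (0.22). Without THP-1 DMSO replicate 2 the amino acid list (-0.13, 0.043), prostaglandin genes (0.25, 0.037) and MYC and ribosome biogenesis genes (-0.19, 0.013) were called, against a median of -0.08 (0.26) for the last with all arrays. The values of the others were -0.16 for anti-apoptotic genes, 0.04 for primary granule genes, 0.07 for eosinophil markers, -0.12 for mitosis, -0.05 for fatty acid synthesis, -0.35 for LXR targets, -0.03 for glycolysis and 0.08 for metallothioneins. They were -0.12 for heat shock genes, 0.15 for MHC class II, -0.10 for histones, -0.10 for the HOXA and MEIS1 program, -0.08 for xenobiotic metabolism and -0.25 for heme and iron genes. Marker lists had -0.09 for erythroid cells, -0.08 for megakaryocytes, -0.48 for T cells, 0.04 for B cells, 0.12 for epithelium and 0.11 for fibroblasts. None of the lists in these 3 sentences had an adjusted p under 0.13, although T cell markers were called under median centring (-0.48, 0.023). Median differences without THP-1 DMSO replicate 2 changed sign for pro-apoptotic genes (-0.05), PPAR targets (-0.04), metallothioneins (-0.23), xenobiotic genes (0.14), megakaryocyte (0.10) and T cell markers (0.07). They were 0.11 for p53 targets, -0.13 for fatty acid synthesis, -0.00 for erythroid markers, 0.17 for fibroblast genes, 0.02 for neutrophil genes, 0.18 for eosinophil markers, -0.14 for LXR targets, 0.31 for MHC class II and -0.31 for the HOXA and MEIS1 program. Adjusted over the list alone, 1 member was higher in THP-1 and 4 were lower in both the amino acid list and the MYC list. In the LXR list 1 was higher and 1 lower, 1 was higher in the anti-apoptotic, neutrophil, fatty acid synthesis and xenobiotic lists, and 0 passed in the others.

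The baseline comparison asked how the untreated lines differed. THP-1 exceeded HL-60 at least 91.4-fold for LAPTM4B, at least 45.4-fold for the carbonic anhydrase CA2 and at least 44.9-fold for TKTL1, which were not above background on the HL-60 DMSO arrays. HMGN3 (log2 difference 6.67 ± 0.15, SE, n = 2 arrays per group, limma adjusted p = 2.3e-07) and the glutathione transferase GSTM3 (6.20 ± 0.18, 6.7e-07) were also higher in THP-1. HL-60 exceeded THP-1 at least 89.9-fold for CST7, at least 82.2-fold for the lectin CLEC2B, at least 38.6-fold for the collagenase MMP1 and at least 22.5-fold for the chemokine CCL2, and S100P (-5.35 ± 0.40, 5.8e-05, and -4.67 without THP-1 DMSO replicate 2) was higher in HL-60 too. In total 1680 probe sets were higher and 1716 lower in THP-1, for 1111 and 1114 genes. Under median centring 426 were higher and 719 lower. The counts were 2125 and 1996 without THP-1 DMSO replicate 2, with 3005 of the 3396 called again in the same direction, and the total was 9089 without THP-1 DMSO replicate 1. It was 1701 and 1858 without HL-60 DMSO replicate 1 and 2.

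Granule and monocyte genes were compared between the lines as a check of the labels planned before the data were examined, and the result was mixed. The granule proteins AZU1 (2.47 ± 0.09), PRTN3 (1.66 ± 0.07) and DEFA4 (1.96 ± 0.34) were higher in THP-1, as was ELANE (0.27 ± 0.06), and CTSG (-0.35 ± 0.07) was higher in HL-60. The homeobox gene MEIS1 was higher in HL-60 (-0.99 ± 0.26), whereas its partner PBX3 (1.98 ± 0.14), the receptor gene FLT3 (2.93 ± 0.33) and the monocyte receptor gene CSF1R (1.24 ± 0.35) were higher in THP-1. These 9 genes passed with limma adjusted p values up to 0.045. Monocyte and macrophage genes went both ways, since CD36 (-4.16 ± 0.16, 3.3e-06) and GPNMB (-5.01 ± 0.11, 2e-07) were higher in HL-60. Counted after the data were seen, 6 of the 14 primary granule genes were higher in THP-1 and 2 in HL-60. Of the 32 monocyte markers 6 were higher in THP-1 and 4 in HL-60. Of the 6 measured genes of the HOXA and MEIS1 program 3 were higher in THP-1 and 1 in HL-60. The plan also named HOXA9, for which no value is given here. The MEIS1 difference was -0.61 without THP-1 DMSO replicate 2. Without THP-1 DMSO replicate 2 the calls of ELANE (0.079) and CSF1R (0.068) were lost.

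The overlap comparison asked whether both lines changed the same genes. PLIN2 was the 1 gene that rose in both lines at an adjusted p of 0.05, where 0.00159 were expected by chance (Fisher's exact test across genes, one-sided p = 0.0016). At an unadjusted p under 0.05, a threshold chosen after seeing the data, 44 genes rose in both (18.2 expected), 26 fell in both (13.6 expected) and 51 moved in opposite directions (31.5 expected). The tests of both lines share 1 estimate of the spread per probe set, so calls coincide in either direction, and these counts do not measure a shared response. ASNS, ANPEP, HMOX1, JUN and DUSP6, chosen after their values were seen, were among the 44. The log2 changes of the 2 lines correlated weakly across genes (Pearson r = 0.07, Spearman rho = 0.06, 11963 genes, which are not independent replicates). Without THP-1 DMSO replicate 2 these were -0.00 and -0.02, and 4 genes rose in both lines at an adjusted p of 0.05. At the unadjusted threshold 87 genes then rose in both (39.9 expected), 42 fell in both (29 expected) and 119 moved in opposite directions (68.1 expected). The overlap at the adjusted threshold was 0 without any 1 of the 4 HL-60 arrays or THP-1 diclofenac replicate 2, under median centring, without the intensity trend and with each line fitted alone. It was 5 without THP-1 DMSO replicate 1.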

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

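The test that leaves THP-1 DMSO replicate 2 out of the 5 list differences and the test of degraded RNA were chosen after the results were seen, and the other tests here were written before their values were seen.

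THP-1 DMSO replicate 2 stood apart from its replicate, with a control median of 78. Raised background could add scatter to dim probe sets first, but the ratio of scatter of dim over bright probe sets was 0.844 (1.96 for dim and 2.32 for bright probe sets, relative to the THP-1 diclofenac pair), so background alone does not account for the scatter. Another cell line under that label would move the array towards HL-60, yet it lay at 0.96 between HL-60 (0) and THP-1 (1) over 155 probe sets, against 0.99 for replicate 1, and admixed HL-60 RNA would raise probe sets bright in HL-60 alone, whose excess over dim ones was 0.12 log2 units. Degraded RNA would raise 3' over 5' signal, but the GAPDH and ACTB ratios were 1.33 and 1.31, and 0 of the 2 exceeded the highest ratio of the other arrays. Poorer hybridisation may remain as a candidate explanation and was not tested.

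Immediate early (0.63), NF-kB (0.54), interferon (0.46), monocyte (0.36) and lysosome (0.34) genes rose more in THP-1 than in HL-60. The outlying array could have made this difference, but the median over members was 0.36 without it and 0.45 with it, and 5 of 5 lists were still called. Members too dim in HL-60 could hide a change there. The 79 members above background on all 8 arrays had a median difference of 0.28. Random signs gave a permutation p of 1e-05, the smallest possible, with members not independent. The lists were chosen because they were called upward in these same values, so this p-value gives no further support. The median difference was 0.45 over all members, so part of it could still come from dim members. A stronger response of the line labelled THP-1 stays open beside this, and no call held with an estimated correlation. The first 28S control differed by 2.22 log2 units between the THP-1 groups (1.86 against THP-1 DMSO replicate 1 alone).

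Other differences between the lines were 0.30 for NRF2 targets, 0.26 for hypoxia genes, 0.20 for ER chaperones, -0.10 for ribosomal proteins, -0.13 for oxidative phosphorylation, -0.14 for DNA replication and -0.24 for cholesterol synthesis. Relative to all genes under the other scalings the last 4 were -0.04, 0.03, 0.02 and -0.05. On the deposited scale these 4 medians themselves were -0.14, -0.07, -0.08 and -0.14, and bright genes had -0.03. The MTDH difference of 1.79 came from 1 of 3 probe sets and was not seen with the other 2, and the cause was not tested.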

How the results depend on the processing

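The fit without both THP-1 DMSO arrays and the overlap at an unadjusted p were chosen after the data were seen. Counts are probe sets called, with all arrays 1 in HL-60, 30 in THP-1, 1 in the interaction, 3396 at baseline, 1 overlap gene, and 7, 14 and 12 lists.

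On the deposited scale the counts were 2, 51 and 2, the overlap 2, and the THP-1 medians of oxidative phosphorylation and ribosomal genes 0.06 and 0.13. Median centring gave 0, 0 and 0, a baseline of 1145 (426 higher, 719 lower), overlap 0, and 2, 10 and 9 lists. It turned primary granule genes in HL-60 to 0.06, DNA replication and oxidative phosphorylation in THP-1 to 0.27 and 0.41, and oxidative phosphorylation in the interaction to 0.12. Relative to all genes, which moved by 0.11, 0.20 and 0.10, these were -0.04, 0.07, 0.22 and 0.03. Bright genes moved by 0.15, 0.33 and 0.16 under centring. No intensity trend gave 0, 0 and 0, overlap 0, and 2, 12 and 8 lists. Without dim probe sets HL-60 had 5 and THP-1 53. The replicate block gave 0 in the interaction, and each line alone 3 in HL-60, 0 in THP-1 and overlap 0. A minimum log2 change of 1 left 19 in THP-1 and 1892 at baseline. With an estimated correlation 1, 0 and 0 lists were called. Without both THP-1 DMSO arrays HL-60 had 7, and the overlap at an unadjusted p was 70. An offset of 16 gave 42 in THP-1 and 3400 at baseline, no offset 32 and 3236, and the other counts stayed. The mean of a gene's probe sets gave 6, 12 and 11 lists. With 1 array left out, HL-60 ranged from 0 (HL-60 DMSO 1) to 11 (THP-1 DMSO 1), THP-1 from 0 (THP-1 diclofenac 2) to 6892 (THP-1 DMSO 1), and the interaction from 0 (HL-60 DMSO 1) to 4042 (THP-1 DMSO 1). Baseline ranged from 1701 (HL-60 DMSO 1) to 9089 (THP-1 DMSO 1) and the overlap from 0 (HL-60 DMSO 1) to 5 (THP-1 DMSO 1). Lists ranged from 4 to 8 in HL-60, 9 to 14 in THP-1 and 5 to 15 in the interaction. The cause of these differences was not tested.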

Other observations

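The genes of the next paragraph were chosen after their values were seen, and the tests of the amino acid response were written before their own values were seen.

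The myeloid peroxidase gene MPO had signals of 41.7, 40.6, 61.2 and 57.8 on the 4 HL-60 arrays and of 201.4, 235.6, 203.9 and 170.6 on the 4 THP-1 arrays, at least 2.13-fold apart with DMSO. Granule genes AZU1 (2.47) and PRTN3 (1.66) were also higher in THP-1, and MEIS1 (-0.99), CD36 (-4.16) and GPNMB (-5.01) in HL-60. In the direction of the labels, CSF1R (1.24), FLT3 (2.93) and PBX3 (1.98) were higher in THP-1 and CTSG (-0.35) in HL-60. CDKN2A had signals of 362.9, 312.7, 314.6 and 308.8 on the HL-60 arrays and of 8.6, 22.5, 42.5 and 17.8 on the THP-1 arrays. The MPO and CDKN2A values are not those usually described for HL-60 cells. The planned check of the labels was mixed and does not decide between the labels, a swap of them and other cells under them, and the lines keep the names of their labels.

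Amino acid response genes rose in both lines. Scaling between arrays could raise a list. Its median under the other scalings was 1 to 2.3 times the value given, a ratio that includes the shift of all genes. On the deposited scale the list had 0.41 in HL-60 and 0.29 in THP-1, and bright genes had -0.01 and -0.03. Under centring it had 0.57 and 0.65, and bright genes had 0.15 and 0.33. Relative to all genes the list median was 0.46 and 0.45, and 4 of 4 tests, which compare with all genes, were called. A general shift of equally bright genes could also raise a list. However, the median lay at percentile 100 in HL-60 and 99.9 in THP-1 among random lists matched on signal. An ATF4-driven response to diclofenac may explain the rise of ASNS, TRIB3 and SLC7A11, and a measurement of ATF4 protein in both lines would test it. In THP-1 the list's call was lost with an estimated correlation, so the hypothesis rests more on HL-60.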
